A study of Mus musculus with 60 samples.

How the data were processed

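Total RNA from mammary glands or fat pads of 20 ovariectomized mice was extracted with Ultraspec, labelled with biotin from 2 µg and hybridised to 3 Affymetrix array types, per the labels' protocols. Lymph nodes were taken out of the glands at collection, per the series' design text. The labels give 4 animals each for V, E and P, 5 for E+P and 3 for E+P CFP. Nothing in the labels gives a batch or a date. The values are the authors' deposited signal intensities on a linear scale, made with MAS5, per the submitters' processing notes; its version and settings are not given in the sources used here. Every array had been scaled before deposit to about the same trimmed mean, from the values themselves, and 3 of all values were at or below 0.

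The 3 arrays that share a group and a replicate number were taken as 1 animal. This was checked with 277 genes present on all array types, each array being matched among the animals of its own group. Chance would give 1 match in each of the 5 groups. Arrays of type A matched their own number best on type B for 13 of 20 animals. Types A and C and types B and C did so for 7 each, little above chance, so the check by genes backs the join only in part. The log2 signal ratio of the 3' to the 5' Gapdh control probe set was also compared over the 20 joined animals. It correlated at 0.969 between types A and B, 0.989 between A and C and 0.976 between B and C. These values go with the join, though the ratio also differed between groups. Probe sets were named from the platform annotation: of 36899, 198 were controls, 29131 had 1 gene symbol, 724 several and 6846 none, and only those with 1 symbol were named. Of these, 29044 were found by gene number in the reference table, and no symbol had to be updated.

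Each array was scaled so that its 2% trimmed mean was common to its array type. Values were then floored at the 25th percentile of the array type (13.6, 28.6 and 19.8 for A, B and C) and turned to log2. A probe set was tested when it lay above the 50th percentile of its array type (61.6, 85.7 and 61.8) in at least 3 animals, which kept 7221, 7716 and 8125 probe sets. A value at the floor has no order below it, so a difference is a lower bound of its size where some animals of the dimmer group are at the floor, and a difference against a group wholly at the floor is given as at least N-fold. Dim probe sets measure differences less well than bright ones, and the arrays carry no count that would give an interval.

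Models were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 5 groups and empirical Bayes moderation with an intensity trend, within each array type. Benjamini-Hochberg adjustment ran over the tested probe sets of all array types together, with a threshold of 0.05. The comparisons were E, P and E+P against V, E+P against E and against P, the interaction, E+P against E+P CFP, and E+P CFP against V. The comparisons, lists, tests and alternatives were chosen before the data were examined, unless said otherwise. A gene was represented by 1 probe set: from A before B before C, then without a special suffix, then with the highest mean.

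The genes named per comparison were the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, up to 4 members with the smallest adjusted p of each list with a call, and a fixed set. The fixed set was Esr1, Pgr, Areg, Greb1, Tnfsf11, Wnt4, Trp53, Cdkn1a, Mdm2, Mki67, Krt8, Krt18, Krt14, Csn2, Wap and Adipoq. The 26 gene lists were estrogen receptor targets, progesterone receptor targets, DNA replication, mitosis, p53 targets, luminal markers, basal markers, milk and secretory genes, adipocyte markers, brown adipocyte markers, fatty acid synthesis, cholesterol synthesis, fibroblast and matrix genes, macrophage markers, lymphocyte and plasma cell markers, endothelial markers, skeletal muscle markers, epidermis markers, peripheral nerve markers, immediate early and stress genes, paracrine and Wnt ligands, interferon response, endoplasmic reticulum folding, clock genes, oxidative phosphorylation and ribosomal proteins. They were tested in 7 of the 8 comparisons, not in E+P CFP against V, with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move one way without setting them against other genes, stood beside it. Members past the threshold were counted over all probe sets and adjusted over the list alone.

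Alternatives fixed in advance were the values as deposited, quantile normalization, median scaling, other floors, an offset, other filters, other variance models, array weights, fits on the compared groups only, the replicate number as a factor, other probe sets per gene, and leaving out each animal. Alternatives added after seeing the data put the lymphocyte score, the skeletal muscle score or the Gapdh ratio in the model, or removed V 4, E 1 and E+P CFP 1 together. Comparisons of single values used two-sided exact permutation tests. Overlaps were set against the product of list sizes over 12232 genes, against 20 simulated unchanged groups, and against splits of the shared animals.

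The procedure was tested on simulated data with 200 of 23062 probe sets changed. For E against V it recovered 3%, 35% and 80% of 1.5-fold, 2-fold and 4-fold changes, and for E+P against V 5.5%, 36% and 83%. For E+P against E it recovered 2.5%, 44.5% and 82%, for E+P against P 2%, 45.5% and 84%, and for the interaction 0.5%, 14% and 64.5%. For E+P against E+P CFP it recovered 3%, 38% and 80.5%, and for E+P CFP against V 2.5%, 31.5% and 78.5%. No change was recovered in the wrong direction. The simulated values were not floored after the change was added, so these shares may be too high for falls of dim probe sets. Unchanged probe sets called by mistake numbered 0 to 14 per simulation, with the most at 4-fold changes (11 in E against V and in E+P against V, 14 in E+P CFP against V). A simulated change in 1 of 26 lists was called by camera at both correlations and by fry, with 0 false calls among the others. The genes of this 1 simulation were drawn independently of each other, so it cannot show how correlated genes affect the list calls.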

Results

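Gene expression was measured in mammary glands of ovariectomized mice, which lack the ovary's steroid hormones, after hormones had been given back. Each animal was injected into the abdominal cavity once a day for 4 days. The vehicle group received 100 µl of sesame oil (V, 4 animals), and the others received 2 µg of 17-beta-estrogen (E, 4 animals), 1 mg of progesterone (P, 4 animals) or both hormones (E+P, 5 animals). The description field of the vehicle samples names progesterone, but their titles and treatment protocols and the design text give sesame oil, and the groups follow the titles. A further group held fat pads without epithelium from 3 animals given both hormones (E+P CFP), to tell the response of the stroma from that of the whole gland. The labels do not say whether these are the animals of the E+P glands or others; they were treated as separate, since the group sizes add up to the 20 animals of the design text only that way. Each of the 20 animals was read on 3 Affymetrix array types, named A, B and C here, which makes 60 arrays. Of 36899 probe sets, 23062 were bright enough to be tested, and they stand for 12232 genes. The 2% trimmed mean of the deposited intensities lay between 150.03 and 150.1 on every array, and the medians lay between 48.4 and 88.3. Changes are log2 differences of group means ± the standard error from limma, with Benjamini-Hochberg adjusted p-values over all tested probe sets. Where animals of the dimmer group were at the floor set for dim values, a difference is a lower bound of its size. The number of animals limits their precision.

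Some animals and groups differed in the tissue and the RNA they held. A score of lymphocyte and plasma cell markers, the mean log2 deviation over the list, was between -1.33 and -1.24 in V 1, V 2 and V 3 but 1.29 in V 4, and lay between 0.33 and 1.63 in the 4 E animals. Glycam1, the lymph node venule mucin that is also a whey protein of milk, was at the floor of 3.76 log2 units in V 1, V 2 and V 3 and at 10.78 in V 4. Skeletal muscle markers scored at least 1.67 in every fat pad and 1.53 in E 1, while no other intact gland exceeded 0.51. The signal ratio of the 3' to the 5' Gapdh control probe set, which grows as RNA degrades, averaged 1.49 ± 0.21 (SD, n = 4) in E against 2.52 ± 0.79 (SD, n = 4) in V. That difference had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 animals allow. V 4 and E+P CFP 1 had the highest ratios, at 3.69 and 4.39.

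**Figure D1:**
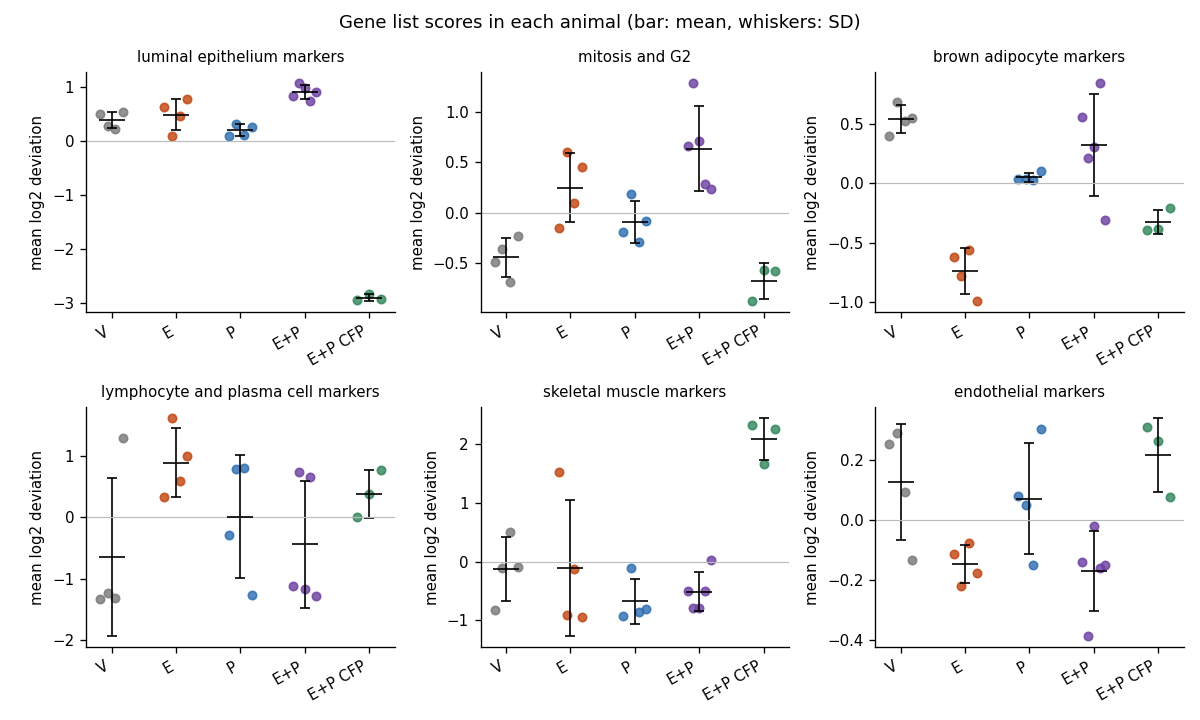
Scores of 6 gene lists per animal (y axis, mean log2 deviation over the list) in the 5 groups (x axis), with group means as bars. The lymphocyte score of V 4 was 1.29 while the other vehicle animals lay at or below -1.24, and the muscle score of E 1, at 1.53, lay next to the lowest of the 3 fat pads, at 1.67.

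Estrogen alone, set against vehicle, raised Fkbp5, Zbtb16 and the mitotic kinase Pbk, and lowered the brown fat genes Ucp1 and Cidea. Fkbp5, a cochaperone of steroid receptors, rose by 1.97 ± 0.31 (adjusted p = 0.00747), and Zbtb16, a zinc finger transcription factor, rose by 2.05 ± 0.37 (adjusted p = 0.0186). Pbk rose by at least 2.24 (adjusted p = 0.00747; 2 vehicle animals at the floor) and the cell division gene Cdca4 by 0.78 ± 0.13 (adjusted p = 0.00882). Tph1, which catalyses the first step of serotonin synthesis, was at the floor in all 4 vehicle animals and at least 8.70-fold higher with estrogen (adjusted p = 0.0174). Ucp1, the uncoupling protein that lets mitochondria make heat, fell by at least 3.23 on the log2 scale (adjusted p = 0.00747; 2 E animals at the floor), and Cidea, a lipid droplet protein of brown adipocytes, fell by 1.64 ± 0.26 (adjusted p = 0.00821). The endothelial genes Cldn5, a tight junction protein, and Cd93 changed by -1.20 ± 0.21 and -1.10 ± 0.17 (adjusted p = 0.0147 and 0.00747). Luminal keratin Krt19 rose by 1.19 ± 0.21 (adjusted p = 0.0186). Further rises were Jpt2 at 2.17, the extracellular peroxidase Gpx3 at 1.34 and the secretory pathway gene Tmed3 at 0.87, with adjusted p-values of 0.0110, 0.00747 and 0.00882. Further falls were Rasl12 at -1.44, the endoplasmic reticulum peroxidase Gpx8 at -1.20, the clock-controlled gene Noct at -1.03, the phosphatase inhibitor Ppp1r1a at -1.0, the fatty acid carrier Fabp5 at -0.98 and the receptor tyrosine kinase Met at -0.93. The adjusted p-values of these 6 were 0.0180, 0.00747, 0.0329, 0.0266, 0.0193 and 0.0409. Another probe set of Jpt2, Gpx3 and Noct moved the other way.

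By list, camera called 8 of 26 in E against V, and the estimated correlation kept 1 of them. Brown adipocyte markers were lower by a mean of -1.28 over 6 members (camera adjusted p = 7.83e-08, and adjusted p = 0.0114 with an estimated correlation). Of these, 2 fell over all probe sets and 4 when adjusted over the list alone, and Cox7a1 and Cox8b, mitochondrial subunits, stood at -1.28 and -0.73 (adjusted p = 0.0988 for both). Mitosis genes averaged 0.69 higher (camera adjusted p = 2.09e-10, and adjusted p = 0.238 with an estimated correlation), with 0 of 30 past the threshold over all probe sets and 8 adjusted over the list alone. Their leading members were the kinase Cdk1 at 1.75 (adjusted p = 0.137), the spindle motor Kif23 at 1.65 (adjusted p = 0.128), the survivin gene Birc5 at 1.5 (adjusted p = 0.0963) and the proliferation marker Mki67 at 1.43 (adjusted p = 0.166). Another probe set of Kif23 moved the other way, and Cdk1 and Kif23 were at the floor in 1 vehicle animal. DNA replication genes averaged 0.39 higher (camera adjusted p = 0.000147, and adjusted p = 0.346 with an estimated correlation). Lymphocyte markers averaged 1.54 higher (camera adjusted p = 3.65e-12, and adjusted p = 0.313 with an estimated correlation), with 12 of 24 past the threshold adjusted over the list alone and 0 over all probe sets. The plasma cell gene Mzb1 stood at 2.55, the B cell genes Cd79a, Cr2 and Ms4a1 at 2.12, 1.45 and 1.44, with adjusted p-values of 0.237, 0.174, 0.192 and 0.201; Mzb1 and Cr2 were at the floor in 3 vehicle animals. Genes of endoplasmic reticulum folding averaged 0.29 higher (camera adjusted p = 0.000115, and adjusted p = 0.286 with an estimated correlation), led by the stress gene Herpud1 at 0.67 (adjusted p = 0.114). Oxidative phosphorylation averaged -0.29 (camera adjusted p = 2.06e-11, and adjusted p = 0.224 with an estimated correlation), adipocyte markers -0.21 (camera adjusted p = 0.00184, and adjusted p = 0.483 with an estimated correlation) and endothelial markers -0.27 (camera adjusted p = 0.00258, and adjusted p = 0.313 with an estimated correlation). The endothelial genes Cdh5 and Esam stood at -0.89 and -0.63 (adjusted p = 0.0744 and 0.174). The lists of estrogen receptor targets, progesterone receptor targets and p53 targets were not called, with means of 0.025, 0.40 and 0.065 and camera adjusted p-values of 0.846, 0.0633 and 0.468. Fkbp5 and Zbtb16 were the 2 of 11 members of the progesterone receptor target list that rose, in animals given no progesterone. Neither passed the threshold in P against V. Of the genes fixed for every comparison, Krt8 stood at 0.85 (adjusted p = 0.0963), Krt18 at 0.28, Wnt4 at 0.60, Mdm2 at 0.27, Cdkn1a at 0.16, Adipoq at -0.25 and the estrogen receptor gene Esr1 at -0.53, none past the threshold.

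In all, 41 of 23062 probe sets passed the threshold in E against V, 18 higher and 23 lower, and they stand for 25 genes; median scaling gave 22 higher and 39 lower. The lymphocyte score was higher by 1.54 in E than in V (two-sided exact permutation p = 0.114) and the Gapdh ratio was lower in E, so both moved with these genes; with the lymphocyte score in the model 7 probe sets passed. The count was 17 without V 2 (12 higher, 5 lower), 14 without V 3 (9 and 5), 142 without V 4 (73 and 69), 20 without E 2 (14 and 6) and 13 without E 4 (8 and 5). It was 28 without V 1 (19 and 9) and 11 with no filter (8 and 3), so falls did not outnumber rises under every setting. Pbk, Fkbp5, Gpx3, Ucp1, Cidea, Gpx8 and Cd93 kept their calls with any 1 animal left out; the other 12 named genes did not, down to Met at -0.78 (adjusted p = 0.20) without E 2. Under every other planned setting together, 0 of the 19 kept their calls.

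Progesterone alone, set against vehicle, changed no single gene past the threshold. The lipogenic genes Acly, which makes cytosolic acetyl-CoA, Elovl6, a fatty acid elongase, and Slc25a1, the mitochondrial citrate carrier, stood at -1.02, -0.93 and -0.73 (adjusted p = 0.450, 0.512 and 0.497). The interferon-induced genes Rsad2 and Usp18 stood at 1.06 and 0.82 (adjusted p = 0.283 and 0.460). The mitotic genes Kif23 and Birc5 stood at 1.26 and 1.20 (adjusted p = 0.464 and 0.415), with 1 vehicle animal at the floor for Kif23 and another probe set of it moving the other way, and Mki67 at 0.37 (adjusted p = 0.867). Ucp1 stood at -1.16 and Cidea at -0.91 (adjusted p = 0.578 and 0.408). Krt8, Krt18, Esr1, Wnt4 and Adipoq stood at 0.067, -0.31, -0.13, 0.18 and 0.20, each with an adjusted p of at least 0.694.

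Camera called 7 of the 26 lists in P against V, and none of these calls held with an estimated correlation. Fatty acid synthesis averaged -0.26 (camera adjusted p = 0.00233, and adjusted p = 0.578 with an estimated correlation) with 2 members lower adjusted over the list alone, and this call ended without V 3 (adjusted p = 0.214). Interferon response averaged 0.25 (camera adjusted p = 0.00193, and adjusted p = 0.578 with an estimated correlation) with 1 member higher adjusted over the list alone, and its call ended without P 4 (adjusted p = 0.170). Mitosis averaged 0.35, oxidative phosphorylation -0.14 and brown adipocyte markers -0.49 (camera adjusted p = 0.000556, 4.61e-05 and 0.0123, and adjusted p = 0.578 with an estimated correlation for all 3). Lymphocyte markers averaged 0.66 (camera adjusted p = 0.000945, and adjusted p = 0.674 with an estimated correlation), and skeletal muscle markers -0.55 (camera adjusted p = 0.0252, and adjusted p = 0.674 with an estimated correlation). The lymphocyte call ended without V 1 (adjusted p = 0.0531), P 2 (0.0634) or P 3 (0.108), and the muscle call without V 3 (0.301), V 4 (0.0531), P 1 (0.123), P 3 (0.113) or P 4 (0.120). Progesterone receptor targets averaged 0.20 (camera adjusted p = 0.260), with 1 member higher adjusted over the list alone.

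By limma, 0 of 23062 probe sets passed in P against V, the smallest adjusted p was 0.0653, and 1856 (8.05%) had an unadjusted p below 0.05. Median scaling gave 1 probe set, a floor at the 40th percentile 3, and no filter on dim probe sets 1. Leaving out V 2, E 3, P 1, P 3 or P 4 gave 3, 1, 3, 4 and 2. On simulated data with 4 animals per group, 77.5% of 4-fold changes and 41.5% of 2-fold changes were recovered in this comparison. The floor was not applied to the simulated values, so these shares may be too high for falls of dim probe sets.

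In whole glands, both hormones together raised the RNA of the cell cycle genes Pbk, Cdk1, Birc5 and Mki67 over vehicle. They lowered that of Rbp7, Timp4 and the endothelial genes Cldn5 and Cdh5. The luminal score averaged 0.90 in E+P and 0.38 in V, and the adipocyte score -0.24 and 0.075. Whether the share of epithelium or the level within cells changed was not tested, here or in the other comparisons of E+P glands. Pbk rose by at least 2.98 (adjusted p = 3.61e-05) and Cdk1 by at least 2.58 (adjusted p = 0.00786), and the nucleotide synthesis genes Tk1 and Rrm2 rose by 2.43 ± 0.51 and at least 2.30 (adjusted p = 0.0352 and 0.0398). Wfdc18, a secreted whey acidic protein family member, rose by 2.72 ± 0.33 (adjusted p = 0.000441), and the thyroid hormone binding protein Crym, at the floor in all vehicle animals, was at least 6.41-fold higher (adjusted p = 0.00606). The retinol binding protein Rbp7, found in adipose endothelium, fell by 2.31 ± 0.22 (adjusted p = 1.05e-05), and Timp4, a metalloproteinase inhibitor, fell by 1.71 ± 0.24 (adjusted p = 0.00161). Further rises were the gap junction gene Gjb2 at 2.40, Serpinb11 at 2.39, the kinetochore gene Cenph at 2.21, Birc5 at 2.08, Mki67 at 2.06, the microtubule regulator Stmn1 at 1.83, the cyclin Ccnb2 at 1.01, the mucin Muc15 at 1.73, the epithelial transcription factor Ehf at 1.55 and the immediate early gene Egr1 at 1.06. Their adjusted p-values were 0.0291, 0.00853, 0.0291, 0.00602, 0.0191, 0.00509, 0.0112, 0.0340, 0.0308 and 0.0308. Further falls were the milk fat globule gene Btn1a1 at -2.08, lactoferrin (Ltf) at -1.58, Clic5 at -1.53, the endothelial repressor Bcl6b at -1.21, Btnl9 at -1.21, Cidea at -1.18, Nrxn3 at -1.14, the clock repressor Nr1d1 at -1.06, Cldn5 at -0.98 and the vascular cadherin Cdh5 at -0.96. Their adjusted p-values were 0.0310, 0.00414, 0.0364, 0.0106, 0.000399, 0.0359, 0.0337, 0.0307, 0.0291 and 0.0291. Kif26a was at the floor in all 5 E+P animals and at least 3.44-fold lower (adjusted p = 0.0307). The sizes for Gjb2, Serpinb11, Cenph and Clic5 are lower bounds too, with animals at the floor. Another probe set of Tk1, Cenph, Bcl6b and Btnl9 moved the other way.

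Camera called 9 of the 26 lists in E+P against V, and none of these calls held with an estimated correlation. Fry, which does not set a list against other genes, called 8 of the 26. Mitosis averaged 1.08 higher (camera adjusted p = 3.69e-20, and adjusted p = 0.0853 with an estimated correlation), with 7 of 30 members rising over all probe sets and 21 adjusted over the list alone. DNA replication averaged 0.71 (camera adjusted p = 3.55e-10, and adjusted p = 0.126 with an estimated correlation), with 2 and 17 of 30. Luminal epithelium markers averaged 0.51 (camera adjusted p = 4.20e-09, and adjusted p = 0.126 with an estimated correlation), with 1 and 10 of 24; Krt19, Krt8, Krt18 and the splicing factor Esrp1 stood at 0.85, 0.81, 0.38 and 1.04 (adjusted p = 0.0670, 0.0700, 0.408 and 0.0506). Adipocyte markers averaged -0.31 (camera adjusted p = 1.66e-07, and adjusted p = 0.189 with an estimated correlation), with 0 of 23 past the threshold over all probe sets and 7 lower adjusted over the list alone. The fatty acid transporter Cd36, lipoprotein lipase (Lpl) and Adipoq, the adiponectin gene, stood at -0.99, -0.62 and -0.29 (adjusted p = 0.0514, 0.0817 and 0.443), with another probe set of Lpl moving the other way. Endothelial markers averaged -0.30 (camera adjusted p = 0.000129, and adjusted p = 0.189 with an estimated correlation), with 2 of 16 lower over all probe sets and 4 adjusted over the list alone. Oxidative phosphorylation averaged -0.20 (camera adjusted p = 2.80e-08, and adjusted p = 0.189 with an estimated correlation) and ribosomal proteins 0.28 (camera adjusted p = 0.000130, and adjusted p = 0.222 with an estimated correlation). Basal markers averaged 0.44 (camera adjusted p = 0.00442, and adjusted p = 0.279 with an estimated correlation) and lost the call without V 4 (adjusted p = 0.0645). Skeletal muscle markers averaged -0.38 (camera adjusted p = 0.0406, and adjusted p = 0.663 with an estimated correlation), a call that ended without V 3 (adjusted p = 0.356), V 4 (0.0633), P 3 (0.0545), E+P 2 (0.121) or E+P 3 (0.140). Genes of p53 response averaged 0.10 (camera adjusted p = 0.395), with Cdkn1a at 0.27 and Mdm2 at 0.084, a value that was -0.047 with median scaling. Esr1 and Wnt4 stood at -0.25 and 0.22. Lymphocyte markers averaged 0.21 (camera adjusted p = 0.495), so they did not move with these groups past the test.

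In all, 106 probe sets passed in E+P against V, 57 higher and 49 lower, and they stand for 79 genes; median scaling gave 47 higher and 73 lower, and the muscle score in the model 36 higher and 19 lower. The count was 67 without V 1 (46 higher, 21 lower), 44 without V 2 (33 and 11), 34 without V 3 (24 and 10), 32 without E+P 2 (21 and 11) and 52 without E+P 5 (32 and 20). Without the intensity trend 47 were higher and 21 lower, and with the compared groups only 30 and 14, so the balance of rises and falls depends on the setting. Pbk, Wfdc18, Crym, Cdk1, Serpinb11, Birc5, Stmn1, Ccnb2, Rbp7, Timp4, Ltf, Bcl6b and Btnl9 kept their calls with any 1 animal left out; the other 16 named genes did not, down to Cidea at -1.02 (adjusted p = 0.151) without V 3. Of the genes called in E against V, 3 of 9 that rose also rose here (Cdca4, Jpt2 and Pbk), and 7 of 16 that fell also fell here (Cd93, Cidea, Cldn5, Fabp5, Gm2a, Gpx8 and Rflnb). Independent lists would share 0.0294 and 0.0510 genes. In 20 simulations with no change in any group the overlap was 0. Almost no gene is called in such groups, so this does not measure what the shared controls add. With the vehicle animals split between the comparisons, over 6 splits, the median overlap was 1 for rises, with a range of 0 to 1, and 0 for falls. These splits left fewer genes called in E against V, a median of 6 rises and 4 falls. The overlaps therefore cannot be set beside 3 of 9 and 7 of 16.

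**Figure D2:**
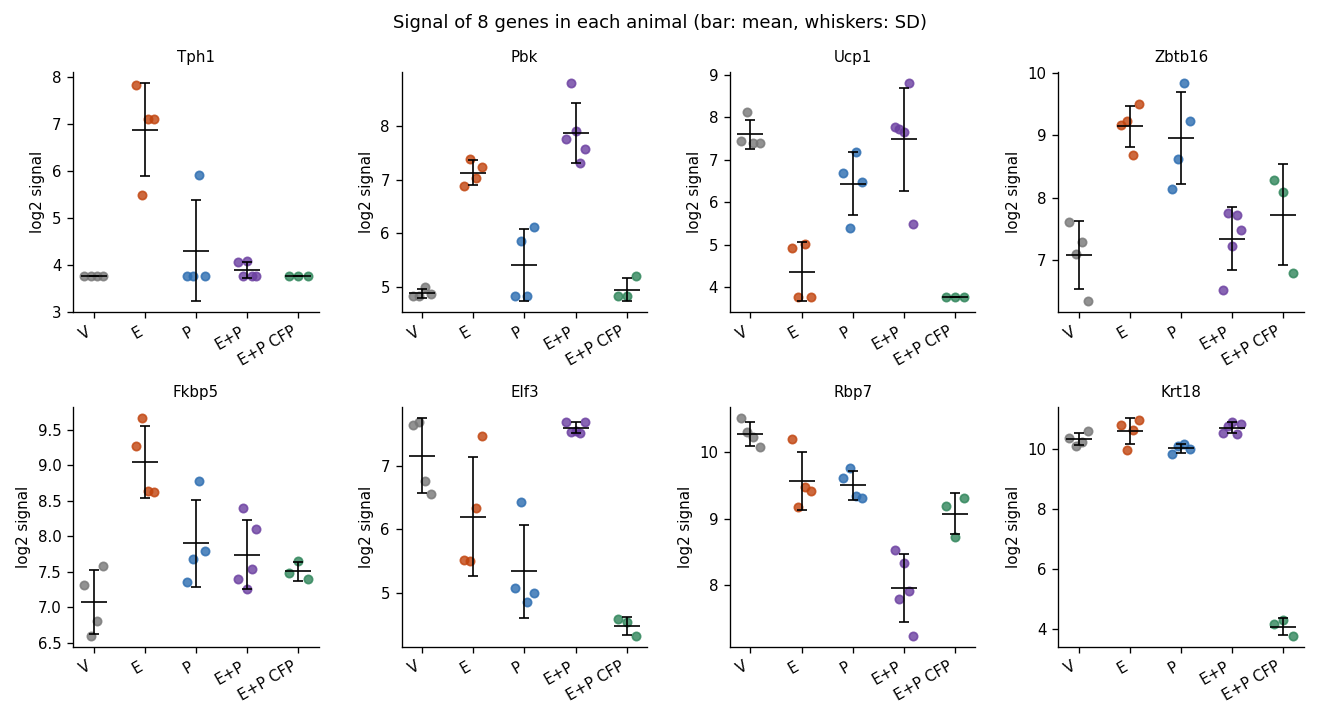
Log2 intensity (y axis) of Tph1, Pbk, Ucp1, Zbtb16, Fkbp5, Elf3, Rbp7 and Krt18 in each animal of the 5 groups (x axis), with group means as bars. Zbtb16 averaged 7.08 in V, 9.14 in E, 8.95 in P and 7.34 in E+P, and Krt18 lay at or below 4.30 in the fat pads.

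Adding progesterone to estrogen, seen in E+P against E, raised Ucp1, Sprr2b and Wfdc18 and lowered Tph1, Ido1 and Zbtb16. Ucp1 was higher by at least 3.12 (adjusted p = 0.00961), while Tph1 fell by at least 2.99 and Zbtb16 by 1.79 ± 0.35 (adjusted p = 0.0173 and 0.0370). The keratinocyte envelope gene Sprr2b rose by 2.90 ± 0.47 and Wfdc18 by 2.08 ± 0.33 (adjusted p = 0.0106 for both), and Ido1, which degrades tryptophan, fell by at least 2.85 (adjusted p = 0.0173). Rbp7 fell by 1.60 ± 0.22 (adjusted p = 0.00621) and Ltf by 1.46 ± 0.24 (adjusted p = 0.0165). Further rises were the Wnt signalling regulator Dact2 at 2.82, Gm15867 at 2.75, Muc15 at 1.81, the atypical cadherin Fat2 at 1.64, the adaptor Gab1 at 1.55, Rasl12 at 1.27, Nrep at 1.20 and the receptor kinase Kit, expressed in luminal progenitors, at 1.05. Their adjusted p-values were 0.0106, 0.0198, 0.0469, 0.0484, 0.00961, 0.0323, 0.0173 and 0.0173. Further falls were 6430571L13Rik at -1.75, the secreted glycoprotein Stc2 at -1.53, Nr1d1 at -1.18, Fam214a at -0.90 and the ceramidase Acer2 at -0.82, with adjusted p-values of 0.0323, 0.0392, 0.0228, 0.0198 and 0.0173. The sizes for Dact2, at the floor in 3 E animals, and Gm15867, in 1, are lower bounds too. Another probe set of Dact2, 6430571L13Rik and Stc2 moved the other way. Mki67 stood at 0.62 (adjusted p = 0.642).

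Camera called 11 of the 26 lists in E+P against E, and 1 held with an estimated correlation. That list, brown adipocyte markers, averaged 1.06 higher (camera adjusted p = 2.14e-05, and adjusted p = 0.0483 with an estimated correlation), with 1 member rising over all probe sets and 3 adjusted over the list alone. Luminal markers averaged 0.41 higher (camera adjusted p = 5.94e-05, and adjusted p = 0.261 with an estimated correlation), with 1 member rising over all probe sets and 9 rising and 1 falling adjusted over the list alone; Ehf stood at 1.41 (adjusted p = 0.0958). Lymphocyte markers averaged -1.33 (camera adjusted p = 3.27e-12, and adjusted p = 0.334 with an estimated correlation) and endoplasmic reticulum folding -0.25 (camera adjusted p = 7.01e-05, and adjusted p = 0.261 with an estimated correlation). Mitosis averaged 0.39 and DNA replication 0.31 (camera adjusted p = 0.00168 and 0.0117, and adjusted p = 0.592 with an estimated correlation for both). Both calls ended without E 1 (adjusted p = 0.0813 and 0.163) and without E+P 2 (adjusted p = 0.149 and 0.288). Paracrine and Wnt ligands averaged 0.39 (camera adjusted p = 0.0427, and adjusted p = 0.261 with an estimated correlation), with 4 higher adjusted over the list alone, led by Wnt5b at 1.82 (adjusted p = 0.0929, 1 E animal at the floor, another probe set moving the other way). Basal markers averaged 0.38, fibroblast and matrix genes 0.23, fatty acid synthesis -0.16 and skeletal muscle markers -0.40 (camera adjusted p = 0.0170, 0.0143, 0.0453 and 0.0117, and adjusted p = 0.592 with an estimated correlation for all 4). The muscle mean was 0.15 (adjusted p = 0.796) without E 1, the intact gland with a muscle score of 1.53, and its call also ended without E+P 2 (0.0548). The Wnt ligand, fibroblast, basal and fatty acid calls each ended without E 2 (adjusted p = 0.0982, 0.0946, 0.0844 and 0.183). Other removals ended them too: E+P 1 (0.105), E+P 4 (0.0624), E+P 5 (0.0806), E+P CFP 2 (0.0515) or E+P CFP 3 (0.0624) for the ligands, E+P 3 (0.0679) or E+P 5 (0.231) for the fibroblast list and E+P 2 (0.0502) for the basal list. For fatty acid synthesis they were E 1 (0.192), E+P 2 (0.229), E+P 3 (0.170), E+P 5 (0.0626) and E+P CFP 3 (0.0530).

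In all, 33 probe sets passed in E+P against E, 17 higher and 16 lower, for 28 genes; median scaling gave 13 higher and 19 lower. The lymphocyte markers were lower in E+P and the Gapdh ratio averaged 2.22 ± 0.51 (SD, n = 5) against 1.49 in E, and 14 probe sets (4 higher, 10 lower) and 10 passed with these in the model. The count was 18 without E 1, 13 without E 2, 18 without E 3, 22 without E 4, 11 without E+P 2 and 21 without E+P 5. Ucp1, Sprr2b, Dact2, Gab1 and Rbp7 kept their calls with any 1 animal left out; the other 16 named genes did not, down to Muc15 at 1.64 (adjusted p = 0.230) without E 2. Under every other planned setting together, 1 of the 21 kept its call.

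Adding estrogen to progesterone, seen in E+P against P, raised the RNA of luminal epithelial genes and lowered that of clock genes, Timp3 and Timp4. The luminal score averaged 0.90 in E+P and 0.19 in P, so a larger share of epithelium is not told apart from changes within cells. The epithelial transcription factor Elf3 rose by 2.26 ± 0.36 (adjusted p = 0.00845), the luminal keratin Krt7 by 1.12 ± 0.19 (adjusted p = 0.0138) and the membrane protease St14 by 1.21 ± 0.23 (adjusted p = 0.0207). Pbk rose by at least 2.45 (adjusted p = 0.00103) and Uhrf1, which maintains DNA methylation at replication, by 2.37 ± 0.34 (adjusted p = 0.00233). Timp4 and Timp3, both metalloproteinase inhibitors, fell by 1.91 ± 0.24 and 0.87 ± 0.12 (adjusted p = 0.00103 and 0.00233). The clock output gene Dbp fell by 1.17 ± 0.22 and Nr1d1 by 1.14 ± 0.21 (adjusted p = 0.0192 and 0.0202). Further rises were Gm15867 at 2.80, Sprr2b at 2.59, Crym at 2.56, the tight junction gene Tjp3 at 2.13, the cholesterol synthesis enzyme Mvd at 2.13, Wfdc18 at 2.12, the Wnt receptor ligand Ndp at 2.06, Stmn1 at 1.56, Ccnb2 at 0.94 and Kit at 0.90. Their adjusted p-values were 0.0144, 0.0175, 0.0138, 0.0175, 0.0175, 0.00652, 0.0413, 0.0202, 0.0205 and 0.0285. Further falls were the potassium channel Kcnk12 at -2.63, Zbtb16 at -1.61, 6430571L13Rik at -1.58, Rbp7 at -1.54, the interferon-induced gene Ifi27l2a at -1.30, the adipokine Rarres2 at -1.08 and C9orf72 at -0.90. These had adjusted p-values of 0.0178, 0.0462, 0.0423, 0.00228, 0.0202, 0.0138 and 0.0175. The sizes for Gm15867, Crym, Tjp3, Mvd and Ndp are lower bounds too, with P animals at the floor. Another probe set of Pbk and Tjp3 moved the other way.

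Camera called 11 of the 26 lists in E+P against P, and 2 held with an estimated correlation. Luminal markers averaged 0.70 higher (camera adjusted p = 3.05e-13, and adjusted p = 0.0300 with an estimated correlation), with 5 of 24 rising over all probe sets and 16 adjusted over the list alone; Krt8 and Krt18 stood at 0.74 and 0.69 (adjusted p = 0.101 and 0.0768). Clock genes averaged -0.33 (camera adjusted p = 0.000747, and adjusted p = 0.0300 with an estimated correlation), with 2 members falling over all probe sets, and 6 falling and 1 rising adjusted over the list alone; Arntl, whose product drives Nr1d1 and Dbp, stood at 1.31 (adjusted p = 0.0510). Mitosis averaged 0.73 and DNA replication 0.64 (camera adjusted p = 3.39e-09 and 5.67e-08, and adjusted p = 0.231 with an estimated correlation for both). Of the mitosis list, 2 of 30 rose over all probe sets, and 14 rose and 1 fell adjusted over the list alone; of the replication list, 7 of 30 rose adjusted over the list alone. Mki67 stood at 1.69 and Tk1 at 2.29 (adjusted p = 0.0644 and 0.0526, another probe set of Tk1 moving the other way). Adipocyte markers averaged -0.30, with 6 lower adjusted over the list alone, basal markers 0.54, with 5 higher, interferon response -0.22 and endothelial markers -0.24 (camera adjusted p = 1.34e-06, 0.000711, 0.00118 and 0.00226, and adjusted p = 0.254 with an estimated correlation for all 4). Ribosomal proteins averaged 0.26 (camera adjusted p = 0.00205, and adjusted p = 0.297 with an estimated correlation), macrophage markers -0.36 (camera adjusted p = 0.0217, and adjusted p = 0.517 with an estimated correlation) and lymphocyte markers -0.45 (camera adjusted p = 0.0191, and adjusted p = 0.691 with an estimated correlation). Cholesterol synthesis was not called, at a mean of 0.22 (camera adjusted p = 0.132), with 1 member, Mvd, rising. The interferon and endothelial calls ended without P 4 (adjusted p = 0.0606 for both), and the macrophage call without P 1 (0.360), E+P 1 (0.101) or E+P 2 (0.0549). The lymphocyte call ended without P 2 (0.363), P 3 (0.328), E+P 1 (0.161), E+P 3 (0.153) or E+P 5 (0.178).

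In all, 81 probe sets passed in E+P against P, 62 higher and 19 lower, for 62 genes; median scaling gave 33 higher and 16 lower, and 145 passed with the lymphocyte score in the model. The count was 52 without P 1, 34 without P 3, 54 without E 3, 19 without E+P 2, 38 without E+P 3 and 44 without E+P 5. Crym, Pbk, Uhrf1, Elf3, Wfdc18, Timp4, Rbp7, Rarres2 and Timp3 kept their calls with any 1 animal left out; the other 17 named genes did not, down to Zbtb16 at -1.32 (adjusted p = 0.146) without P 3.

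The interaction of the hormones asks whether estrogen acts differently when progesterone is present. Zbtb16 averaged 7.08 log2 units in V, 9.14 in E, 8.95 in P and 7.34 in E+P, so each hormone alone went with a higher level than both together (interaction -3.66 ± 0.50, adjusted p = 0.00994). Ucp1 averaged 7.60, 4.36, 6.44 and 7.49 (interaction at least 4.28, with 2 E animals at the floor, adjusted p = 0.0131), and Elf3 averaged 7.16, 6.20, 5.34 and 7.59 (interaction 3.22 ± 0.53, adjusted p = 0.0139, another probe set moving the other way). Kcnk12 averaged 6.25, 7.57, 8.32 and 5.70 (interaction -3.94 ± 0.72, adjusted p = 0.0280). The remaining called genes were Gm15867 at 4.44, Sprr2b at 3.67, the zinc transporter Slc30a2 at 3.35, the kinase gene Mast2 at 1.65 and 6430571L13Rik at -2.71. Their adjusted p-values were 0.0123, 0.0366, 0.0185, 0.0280 and 0.0280, and the size for Gm15867, with E and P animals at the floor, is a lower bound. Slc30a2 was at the floor in 4 E, 3 P and 1 E+P animals, which pull the value both ways, so its size is not exact. Fkbp5 averaged 7.08, 9.05, 7.90 and 7.74, with an interaction of -2.14 (adjusted p = 0.0583), and the tight junction gene Cldn4 stood at 2.21 (adjusted p = 0.0856).

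Camera called 8 of the 26 lists in the interaction, and brown adipocyte markers, at a mean of 1.55, held with an estimated correlation (camera adjusted p = 6.54e-06, and adjusted p = 0.0332 with an estimated correlation). Of these, 1 member was called over all probe sets and 4 adjusted over the list alone. Luminal markers averaged 0.60 and endoplasmic reticulum folding -0.40 (camera adjusted p = 6.95e-05 for both, and adjusted p = 0.333 with an estimated correlation), with 1 luminal member called over all probe sets and 8 adjusted over the list alone. Oxidative phosphorylation averaged 0.23 (camera adjusted p = 6.95e-05, and adjusted p = 0.446 with an estimated correlation). Lymphocyte markers averaged -1.99 (camera adjusted p = 3.72e-12, and adjusted p = 0.336 with an estimated correlation), with 10 members lower adjusted over the list alone. Clock genes averaged -0.33 (camera adjusted p = 0.0248, and adjusted p = 0.220 with an estimated correlation), a call that ended without E 3 (adjusted p = 0.0606) or P 3 (0.0601). Macrophage markers averaged -0.61 and basal markers 0.49 (camera adjusted p = 0.0142 and 0.0483, and adjusted p = 0.565 with an estimated correlation for both). The macrophage call ended without V 1 (adjusted p = 0.275), E 2 (0.0984) or P 1 (0.131), and the basal call without any 1 of 10 animals, with adjusted p-values from 0.0572 without E 1 to 0.213 without V 1.

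In all, 17 probe sets passed for the interaction, 8 above and 9 below 0, for 9 genes; median scaling gave 12 above and 15 below. With other terms, 9 passed with the lymphocyte score and 4 with the Gapdh ratio in the model. The count was 10 without V 2, 47 without V 4, 27 without E 1 and 45 without P 4. Gm15867, Ucp1, Slc30a2 and Zbtb16 kept their calls with any 1 animal left out; the other 5 did not, down to Sprr2b at 3.51 (adjusted p = 0.102) without V 2.

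The intact gland was set against the fat pad without epithelium, both from animals given both hormones. The luminal keratins Krt18, Krt19 and Krt8 were at least 99.4-fold, at least 103-fold and at least 94.1-fold higher in the gland (adjusted p = 1.55e-15, 1.64e-14 and 1.52e-14). For Krt18 only 1 fat pad was at the floor, the others lying at 4.19 and 4.30 log2 units. The luminal transcription factor Foxa1 was at least 40.2-fold higher and Elf5, which drives alveolar development, at least 14.1-fold (adjusted p = 4.33e-12 and 1.03e-10). The casein gene Csn3 was higher by at least 5.06 (adjusted p = 1.52e-07), Lcn2, an iron-trapping lipocalin, by at least 5.04 (adjusted p = 1.21e-09) and Ltf by at least 3.90 (adjusted p = 1.66e-09). Of skeletal muscle genes, the myosin Myh4 was lower in the gland at -5.34 (adjusted p = 0.00549, another probe set moving the other way) and the troponin Tnnt3 at -4.48 (adjusted p = 0.000534), both lower bounds of the size, with 1 and 4 E+P animals at the floor. Krt7 was at least 40.2-fold higher, the placental surface antigen gene Plet1 at least 37.2-fold, Muc15 at least 11.9-fold, the desmosomal p53 target Perp at least 10.1-fold and Ucp1 at least 13.2-fold (adjusted p = 4.70e-13, 5.40e-12, 1.62e-06, 7.90e-11 and 5.70e-05). Tlcd4 and the ion transport regulator Fxyd3 stood at 5.48 and 5.27 or more (adjusted p = 3.20e-12 and 4.62e-12), with another probe set of Tlcd4 moving the other way.

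Of the luminal list, 23 of 24 members were higher in the gland, over all probe sets and adjusted over the list alone, at a mean of 3.80 (camera adjusted p = 2.40e-53, and adjusted p = 5.56e-05 with an estimated correlation); the mucin Muc1 stood at 2.55 (adjusted p = 2.01e-08). Estrogen receptor targets averaged 1.07 higher (camera adjusted p = 2.08e-06, and adjusted p = 0.00616 with an estimated correlation), with 9 of 17 higher, and 10 higher and 1 lower adjusted over the list alone; Esr1 itself stood at 0.51 (adjusted p = 0.154). The other 15 of 17 camera calls were lost with an estimated correlation. Basal markers averaged 1.30, progesterone receptor targets 0.68, immediate early genes 0.63, skeletal muscle markers -2.60, fatty acid synthesis -0.71 and adipocyte markers -0.64, each with an adjusted p = 0.0523 with an estimated correlation. Their camera adjusted p-values were 8.11e-08, 0.00137, 0.000704, 7.42e-17, 4.95e-10 and 5.24e-11. Of the basal list 7 of 12 were higher, and 10 adjusted over the list alone, among them Cnn1 at 3.08 or more and Acta2 at 1.39, contractile genes of myoepithelium (adjusted p = 2.34e-07 and 0.000272, another probe set of Acta2 moving the other way). Of progesterone receptor targets 4 of 11 were higher, both over all probe sets and adjusted over the list alone. Of the immediate early and stress list 6 were higher, and 7 higher and 1 lower adjusted over the list alone, with the heat shock gene Hspa1b at 2.58 (adjusted p = 6.10e-08). Of the muscle list 17 of 21 were lower in the gland, and 18 adjusted over the list alone, with Myh1 at -4.30, Cox6a2 at -3.92, Myom2 at -3.90 (another probe set moving the other way), Actn3 at -3.86, Ryr1 at -3.23, Mb at -3.22, Tnnc2 at -3.19 and Acta1 at -4.54, of which Acta1 lost its call without E+P CFP 1 or E+P CFP 3 (adjusted p up to 0.0639); for Myh1, Cox6a2, Myom2, Actn3, Ryr1 and Mb, with E+P animals at the floor, the sizes are lower bounds. Of fatty acid synthesis 9 of 17 were lower, and 15 adjusted over the list alone, with Acly at -1.52 and the transcription factor Srebf1 at -0.84 (adjusted p = 0.00488 and 0.00153). Of adipocyte markers 13 of 23 were lower, and 18 lower and 1 higher adjusted over the list alone, with the adipocyte regulator Pparg at -1.30, Cd36 at -1.27, Lpl at -0.93 and Adipoq at -0.59 (adjusted p = 0.00228, 0.00178, 0.000831 and 0.0153, and 0.0885 for Adipoq without E+P CFP 1).

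Cell division genes were also higher in the gland than in the fat pad. Mitosis averaged 1.31 with 16 of 30 members higher, and 23 adjusted over the list alone (camera adjusted p = 1.21e-11, and adjusted p = 0.0533 with an estimated correlation), with Cdk1 at 2.96 and Mki67 at 2.74 (adjusted p = 0.000290 and 0.000202). DNA replication averaged 0.90 with 13 of 30 higher, and 16 adjusted over the list alone, while endothelial markers averaged -0.39 with 2 lower, and 5 adjusted over the list alone (camera adjusted p = 7.34e-07 and 0.000386, and adjusted p = 0.0806 with an estimated correlation for both); Cdh5 stood at -1.12 (adjusted p = 0.00128). Oxidative phosphorylation averaged -0.39 with 15 of 34 lower, and 23 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.62e-11, and adjusted p = 0.0533 with an estimated correlation). Ribosomal proteins averaged 0.53 with 8 of 20 higher, and 14 adjusted over the list alone (camera adjusted p = 5.42e-07, and adjusted p = 0.0598 with an estimated correlation), Rpl10a standing at 0.95 (adjusted p = 4.01e-05). Milk and secretory genes averaged 1.07 with 5 of 11 higher (camera adjusted p = 0.000880, and adjusted p = 0.0659 with an estimated correlation). Cholesterol synthesis averaged -0.40 with 3 lower, and 5 adjusted over the list alone (camera adjusted p = 0.00224, and adjusted p = 0.0748 with an estimated correlation). Lymphocyte markers averaged -0.82 (camera adjusted p = 0.00190, and adjusted p = 0.570 with an estimated correlation). Paracrine and Wnt ligands averaged 0.60 with 4 higher and 1 lower (camera adjusted p = 0.0181, and adjusted p = 0.0765 with an estimated correlation), a call that ended without E+P CFP 3 (adjusted p = 0.0891); the 1 lower was Fgf10, a stromal growth factor, at -1.79 (adjusted p = 0.000262), and Wnt4 stood at 0.51 (adjusted p = 0.278). The p53 list was not called (camera adjusted p = 0.464): the kinase gene Plk2 rose with Perp, at 1.90, and the DNA damage gene Gadd45a fell, at -1.47 (adjusted p = 4.01e-07 and 0.00426). Epidermis and peripheral nerve markers were called in none of the 7 comparisons tested by list; here the epidermis list had a camera adjusted p of 0.741.

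In all, 1823 probe sets passed in E+P against E+P CFP, 1206 higher and 617 lower in the gland, for 1278 genes. Median scaling, which moved the median of all probe sets to -0.12, gave 827 higher and 1226 lower. Muscle markers moved with the fat pads, so genes lower in the gland are not shown to be stromal. With the muscle score in the model 237 probe sets passed, 227 higher and 10 lower. The score did not overlap between E+P (-0.80 to 0.023) and the fat pads (1.67 to 2.32). This fit therefore takes out other differences between the groups too and cannot decide which genes go with muscle. The count was 1087 without E+P CFP 1, and 40 of the 42 named genes kept their calls with any 1 animal left out.

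Set against vehicle-treated glands, the fat pads were lower in Krt18, Csn3, Fam25c and Krt19 and higher in Actn3, Tnnt3 and Myh1; gene lists were not tested here. Krt18 was at -6.25 and Csn3 at -6.13, both lower bounds of the size with 1 and 2 fat pads at the floor, Fam25c at least 61.6-fold lower and Krt19 at least 57.1-fold lower (adjusted p = 1.24e-14, 2.01e-08, 6.76e-10 and 5.84e-13). The sarcomere genes Actn3, Tnnt3 and Myh1 were higher by at least 4.18, at least 3.79 and 3.75 ± 0.71 (adjusted p = 0.000532, 0.00758 and 0.00304). In all, 708 probe sets passed, 158 higher and 550 lower, for 500 genes, and median scaling gave 204 higher and 421 lower. The count was 471 without E+P CFP 1 and 194 with the muscle score in the model, 9 higher and 185 lower. This comparison holds the hormones and the missing epithelium at once, since a fat pad from vehicle-treated animals was not analysed here.

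Of the 40 genes that rose in E+P against V, 37 were also higher in the gland than in the fat pad, where independent lists would share 2.76. Among them 6 were called lower in the fat pad than in the vehicle gland: Wfdc18, Muc15, Igsf9, Col7a1, Slco2a1 and Mpzl1, the last 4 named after their values were seen. The exceptions were Egr2, Bub1b and Lmo4, and Egr2, an immediate early transcription factor, was the 1 rise also called in the fat pad against V, where 0.330 were expected. Of the 39 genes that fell, 28 were lower in the gland than in the fat pad (1.38 expected), 2 were higher (Btn1a1 and Ltf), and 8 were also lower in the fat pad than in V (1.27 expected). These comparisons share animals. Simulated 20 times with no change in any group, they gave 0 shared genes. Almost no gene is called in such groups, so this does not measure what the shared animals add. With the E+P animals split over 10 splits, the overlap was 2 for rises (median, range 1 to 54) and 3.5 for falls (median, range 1 to 21). These splits left fewer genes called in E+P against V, a median of 2 rises and 4.5 falls. The smaller overlaps therefore cannot be set beside 37 and 28. With the vehicle animals split, the overlap was 0 for rises and 1 for falls (median, range 0 to 2), where a median of 8 rises and 8 falls were called in E+P against V.

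**Figure D3:**
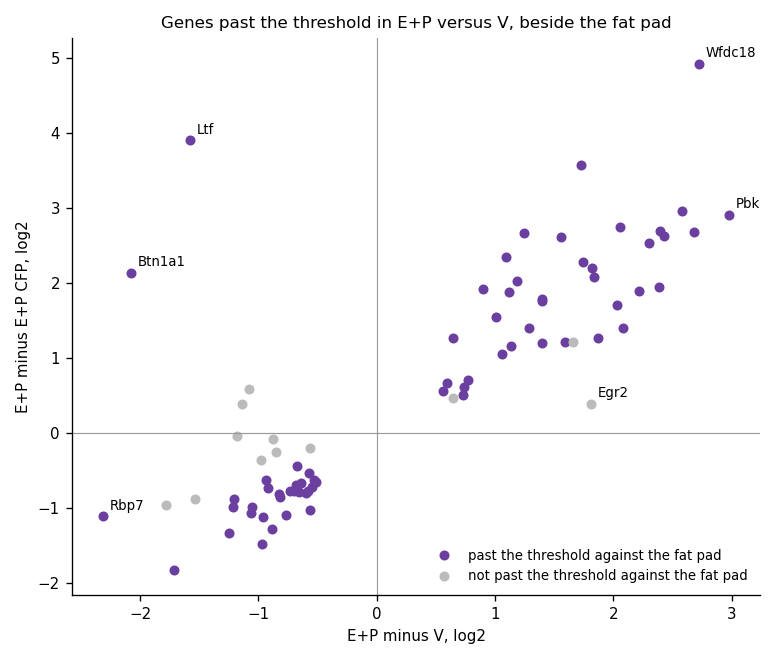
Log2 difference E+P minus E+P CFP (y axis) against E+P minus V (x axis) for the 79 genes called in E+P against V, each point a gene. Of the 40 genes to the right, 37 were called higher than in the fat pad, and of the 39 to the left, 28 were called lower.

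Of the genes fixed in advance, Pgr, Greb1, Tnfsf11, Krt14, Csn2 and Wap had probe sets that were too dim to be tested, and Areg and Trp53 had no probe set with a single symbol used here.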

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

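The tests of other splits of the animals and of lymphocyte RNA behind the E against V genes were set before their values were seen; the tests of Glycam1, of the estrogen effect on lymphocyte markers, of the brown adipocyte list and of the clock genes were chosen after the results were seen.

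The animals of each comparison were also split into other groups of the same sizes. In E against V, 1 of 35 splits, the real one, called as many as 41 probe sets, and the highest other called 4. That share, 0.0286, is the smallest that 35 splits allow, so chance is unlikely but not excluded. The real split also called the most in E+P against V (1 of 100 splits, real 106, highest other 8), E+P against E (1 of 100, real 33, highest other 4) and E+P against P (1 of 100, real 81, highest other 4). So it did in E+P against E+P CFP (1 of 56, real 1823, highest other 18) and E+P CFP against V (1 of 35, real 708, highest other 160). For the interaction (1 of 100, real 17, highest other 3) the labels of V, E, P and E+P were shuffled together. That also breaks up the effects of the single hormones, so this count cannot decide about chance for the interaction alone. In P against V the real count was 0, which all 35 splits reach whatever the data hold, so this test decides nothing there; the highest other called 64. That split set P 4 with V 1, V 2 and V 3 against P 1, P 2, P 3 and V 4, which parts the animals with low lymphocyte scores from the others and points to a structure of the samples.

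Lymphocyte markers differed between animals of 1 group: V 4 scored 1.29 against a mean of -1.30 in the other vehicle animals, and the heavy chain gene Ighm was at 10.19 in V 4 and at most 7.81 in the others. Lymphocyte RNA as the source of the E against V calls is argued against: its slope within groups predicted a median of 4.07% of the change of the 25 called genes (standard error 2.40%, range -11.0% to 26.4%), and over 50% for 0 of them. With the score in the model the count fell to 7 because the median size of these changes went from 1.10 to 0.94 while their median standard error went from 0.190 to 0.219; all 25 kept their sign. Lymph node tissue carried into some glands remains a candidate explanation. Glycam1 and the score lay on the same side of their group means in 16 of 20 animals, 1 short of the number set for it. That count holds a near-tie: E+P CFP 2 scored 0.378 against a group mean of 0.384. By level, Glycam1 was at the floor of 3.76 in V 1, V 2, V 3, P 4 and E+P 5. These had the lowest scores, at or below -1.24. In every other animal Glycam1 was at least 5.33 and the score at least -1.17. Epithelium is not needed as the source of Glycam1, since it lay between 9.61 and 10.41 in the fat pads. Estrogen is argued against as the cause of the spread within groups. Scores ran from -1.33 to 1.29 in V and from -1.27 to 0.81 in P, which received none. In E+P, where every animal received it, they ran from -1.29 to 0.74. A rise of the mean score with estrogen in E against V stays open, at a two-sided exact permutation p of 0.114 with 4 against 4 animals. V 4, given no estrogen, had Glycam1 at 10.78, within the range of the E animals (10.27 to 11.79). Such levels therefore do not need estrogen, and the difference of E against V goes with lymph node tissue. A part due to estrogen is not excluded, since every E animal had high Glycam1.

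Brown adipocyte markers were lower in E, led by Ucp1 and Cidea, and their score lay between -0.99 and -0.56 in E and between 0.40 and 0.68 in V. Dilution of all fat by other tissue is argued against, since the brown score less the adipocyte score was still -1.07 in E against V (standard error 0.127, two-sided exact permutation p = 0.0286, the smallest possible). Lymph node tissue is argued against as well: the list's mean change was -1.35 with the lymphocyte score in the model (camera adjusted p = 3.30e-08). With the Gapdh ratio in the model it was -1.42 (camera adjusted p = 2.74e-08). The ratio did not overlap between E (1.24 to 1.72) and V (1.97 to 3.69), so this fit cannot exclude RNA quality. Cidea also fell in E+P against V (-1.18, adjusted p = 0.0359), a call that 7 removals of 1 animal ended, but the brown list was not called there (camera adjusted p = 0.167), and its score averaged 0.32 in E+P and -0.33 in the fat pads against 0.54 in V. A response of brown fat cells to estrogen and fewer such cells in the tissue taken from the E animals are hypotheses that stay open and were not tested.

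Dbp and Nr1d1 fell in E+P against P, and 8 clock genes in phase with Dbp, these 2 included, averaged -0.48 in E+P against the other intact glands. The 8 were chosen after those falls were seen, so their mean restates the pattern and does not test it. Dbp lay between 6.81 and 7.75 in E+P, overlapping V (7.29 to 8.13), and between 8.36 and 8.89 in P. Its fall against P thus also holds a high level in P. In the fat pads, given both hormones too, Nr1d1 lay between 7.96 and 8.30 and Dbp between 7.87 and 8.25. The whole clock list scored -0.12 there, near the -0.16 of E+P. Collection of the E+P glands at another time of day could give this, and would move the 5 genes of opposite phase the other way. Their mean difference was -0.00232 (standard error 0.137, two-sided exact permutation p = 0.984), a value near 0 over genes that moved both ways, which excludes neither that nor an effect of the hormones. The labels give no time of collection, so the explanations cannot be told apart.

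The effect of estrogen differed with and without progesterone, by the interaction test, for 9 genes and 1 list, counting only lists called by camera with both the preset and the estimated correlation; the preset alone called 8 of 26. The differences were 4.44 for Gm15867, 4.28 for Ucp1, 3.67 for Sprr2b, 3.35 for Slc30a2, 3.22 for Elf3, 1.65 for Mast2, -2.71 for 6430571L13Rik, -3.66 for Zbtb16 and -3.94 for Kcnk12, and 1.55 for the brown adipocyte list. With animals at the floor, the values for Gm15867 and Ucp1 are lower bounds and that for Slc30a2 is not exact.

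Among 616 sets of 4 or 5 animals, 57 held an animal apart from its group by Dixon's test, 13 for lists and 44 for genes, where chance gives 1 in 20, or 30.8. That rate does not apply to the 29 sets with several animals at the floor, of which 14 held an animal apart. In 13 of these all other animals were at the floor, so any value above it passes, however close (E 4 in Dact2 was at 4.39 against 4.31). Among the 587 sets without ties, 43 held an animal apart, where chance gives 29.4. For list scores, in V, the animals apart were V 4 at 1.29 for lymphocyte and -0.20 for adipocyte markers, V 3 at 0.40 for fatty acid synthesis and V 2 at 0.11 for interferon response. Among single-hormone groups they were E 2 at -0.42 for paracrine and Wnt ligands, P 1 at 0.49 for fibroblast and 0.67 for macrophage genes, P 2 at -0.10 for skeletal muscle markers and P 4 at 0.10 for brown adipocyte markers. In E+P they were E+P 2 at 1.02 for DNA replication and -0.064 for estrogen receptor targets, E+P 4 at 0.17 for basal markers and E+P 5 at -0.60 for milk and secretory genes.

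For genes, given as log2 intensity, V 4 was high in Ms4a1 (8.56), Mzb1 (7.54), Cr2 (5.86), Cenph (5.24) and Serpinb11 (5.07) and low in Adipoq (13.02), Esr1 (9.11) and Cldn5 (8.18). The other vehicle animals apart were V 1 in Slc30a2 (7.21), V 2 in Ucp1 (8.13) and V 3 in Slc25a1 (11.64), all high. E 1 was high in Esam (8.72), Myom2 (7.97) and Cox6a2 (7.09) and low in Tk1 (4.87), and E 2 was high in Lcn2 (10.31) and low in Adipoq (12.64) and Cdh5 (8.63). E 3 was high in Kif26a (5.93) and low in Mdm2 (6.94), and E 4 was high in Gm15867 (6.25) and Dact2 (4.39). P 1 was high in Crym (4.25) and low in Lcn2 (7.95), and P 2 was high in Acta1 (7.07), Elf3 (6.42), Ryr1 (4.96), Tnnt3 (4.70) and Slc30a2 (4.34). P 3 was high in Cenph (6.58) and Tph1 (5.92) and low in Cldn5 (6.97), and P 4 was high in Gm15867 (6.14) and low in Mdm2 (6.79) and Cd79a (5.16). E+P 2 was low in Btnl9 (8.85) and Rarres2 (8.40), and E+P 4 was low in Slc30a2 (4.31). E+P 5 was high in Acta1 (8.07), Cdkn1a (7.0), Tnnc2 (6.63), Tnnt3 (6.06) and Ryr1 (5.13) and low in Cox8b (6.84).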

How the results depend on the processing

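Alternatives with the lymphocyte score, the skeletal muscle score or the Gapdh ratio in the model, and the removal of V 4, E 1 and E+P CFP 1 together, were chosen after seeing the data; all others were planned. The values as deposited kept the calls of the 153 called named genes and 71 called list results, and the 8 counts stayed within 1.5 times the main ones (42 in E against V, 107 in E+P against V, 84 in E+P against P and 713 in E+P CFP against V). With any 1 animal left out 85 of the 153 named genes kept their calls, under every other planned setting 61 did, and 60 did under both. The 61 were 39 of 42 in E+P against E+P CFP, 6 of 7 in E+P CFP against V, 8 of 29 in E+P against V, 5 of 26 in E+P against P, 2 of 9 for the interaction, 1 of 21 in E+P against E and 0 of 19 in E against V. Of the 71 list results an estimated correlation kept 7 and fry called 32; camera was not run with the robust variance model. Over all 26 lists, fry called 2 in E against V, 0 in P against V and 8 in E+P against V. It called 1 in E+P against E, 6 in E+P against P, 1 for the interaction and 18 in E+P against E+P CFP. Signal over background limits dim probe sets: with more of them tested or floored, the counts changed as given here.

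The main counts were 41 (E against V), 0 (P against V), 106 (E+P against V), 33 (E+P against E), 81 (E+P against P), 17 (interaction), 1823 (E+P against E+P CFP) and 708 (E+P CFP against V). The cause of the changes was not tested unless given. Median scaling gave 1 in P against V, 49 in E+P against P and 27 for the interaction. The floor at the 40th percentile gave 3 in P against V, 50 in E+P against E and 123 in E+P against P. With no filter, where more probe sets share the adjustment, 11 passed in E against V, 1 in P against V, 45 in E+P against V, 16 in E+P against E and 52 in E+P against P. Without the intensity trend, 68 passed in E+P against V. Array weights gave 282 in E against V, 210 in E+P against V, 73 in E+P against E and 36 for the interaction. Fits on the compared groups only, which have fewer animals to estimate the spread, gave 44 in E+P against V, 10 in E+P against E, 25 in E+P against P and 418 in E+P CFP against V.

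The lymphocyte score as a covariate gave 7 in E against V, 14 in E+P against E, 145 in E+P against P and 9 for the interaction, and put the fibroblast list in E+P against E at a mean of 0.0020, with the camera direction turned (adjusted p = 0.511). The muscle score gave 55 in E+P against V, 237 in E+P against E+P CFP and 194 in E+P CFP against V. The Gapdh ratio gave 10 in E+P against E and 4 for the interaction. Removing V 4, E 1 and E+P CFP 1 gave 83 in E against V, 15 in E+P against E, 1076 in E+P against E+P CFP and 369 in E+P CFP against V, and the muscle list in E+P against E turned to 0.15.

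With 1 animal left out, the counts ran from 13 (E 4) to 142 (V 4) in E against V, 0 (V 1) to 4 (P 3) in P against V, 32 (E+P 2) to 140 (P 3) in E+P against V and 11 (E+P 2) to 37 (P 3) in E+P against E. They ran from 19 (E+P 2) to 101 (E+P 4) in E+P against P, 10 (V 2) to 47 (V 4) for the interaction, 1087 (E+P CFP 1) to 1997 (P 3) in E+P against E+P CFP and 471 (E+P CFP 1) to 772 (P 3) in E+P CFP against V. The muscle list in E+P against E ran from -0.67 (E 4) to 0.15 (E 1).

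Genes that changed sign with 1 animal left out were all uncalled: in P against V, Krt8 (-0.066 to 0.20) and Wnt4 (-0.039 to 0.36); in E against V, Cdkn1a (-0.25 to 0.43); and in E+P against V, Wnt4 (-0.0056 to 0.41), Mdm2 (-0.032 to 0.18) and Cdkn1a (-0.13 to 0.54). Median scaling turned Krt8 in P against V to -0.032 and Mdm2 in E+P against V to -0.047. The probe set with the highest mean turned Jpt2 to -0.092, Noct to 0.43 and Kif23 to -0.28 in E against V, Kif23 to -0.10 in P against V, Dact2 to -0.27 in E+P against E and Elf3 to -0.20 for the interaction. The mean over probe sets turned Esr1 to 0.026, 0.31 and 0.037 in E, P and E+P against V, and Cdkn1a to -0.18 in E+P against V. Here another probe set was read, which is the cause.

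The replicate number as a block gave 2 in P against V, 46 in E+P against V, 2 in E+P against E, 33 in E+P against P and 11 for the interaction, and moved no other count by over 1.5 times. The numbers did not clearly pair the animals: deviations of same-numbered animals correlated at -0.19 to 0.15, and no pair of groups had every correlation over 0.1. Animals correlated best with their own number in 3 of 3 cases for E and E+P CFP and 3 of 4 for E and E+P. For V and E+P CFP and for E+P and E+P CFP it was 0 of 3. Something shared by number is therefore not excluded. The block also takes out E+P 5, the only animal with that number. Leaving it out alone gave 52 in E+P against V, 21 in E+P against E, 44 in E+P against P and 15 for the interaction, so the lower counts are not due to the block alone.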

Other observations

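The genes named in this part were chosen for it after their values were seen. Except for Rbp7, Cidea, Btn1a1 and Ltf in E+P against V, their calls here were not followed with animals left out. In E+P against V, 4 further genes rose and were also higher in the gland than in the fat pad: Igfbp2, an insulin-like growth factor binding protein, by 1.74 ± 0.28 (adjusted p = 0.00488), the methylation maintenance gene Uhrf1 by 1.82 ± 0.34 (adjusted p = 0.0155), the transcription factor Etv5 by at least 1.39 (1 vehicle animal at the floor, adjusted p = 0.0417) and the basement membrane anchor Col7a1 by 1.09 ± 0.24 (adjusted p = 0.0455). Egr2 rose by 1.81 ± 0.31 (adjusted p = 0.00930) and, unlike these, also stood higher in the fat pad than in V, by 1.43 ± 0.35 (adjusted p = 0.0268).

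Further genes fell in E+P against V. The epoxide hydrolase Ephx2 stood at -1.25 ± 0.28, the lysosomal activator Gm2a at -1.05 ± 0.15, the triglyceride synthesis enzyme Gpat3 at -0.97 ± 0.18 and the adiponectin receptor Adipor2 at -0.70 ± 0.15 (adjusted p = 0.0474, 0.00357, 0.0148 and 0.0345). All 4 were lower in the gland than in the fat pad, at -1.34, -0.99, -1.47 and -0.77. The endothelial genes Cd93 and Sox7, a transcription factor, stood at -0.94 ± 0.16 and -0.64 ± 0.14 (adjusted p = 0.00958 and 0.0474). Rbp7, Cidea and Gpx8 were lower than in V both in the intact E+P glands and in the E+P CFP fat pads, where they stood at -1.20, -1.14 and -0.80. Btn1a1 and Ltf stood at -4.20 and -5.48 in the fat pads, lower bounds of the size with 3 and 1 fat pads at the floor.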
